A study of Mus musculus with 8 samples.

How the data were processed

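RNA from mouse mammary basal cells, sorted by cell cycle phase into G0 and G1, was sequenced in 8 libraries, 4 per phase. Per the labels, polyadenylated RNA was selected with oligo-dT beads, stranded libraries were built with the Illumina TruSeq kit, and paired-end reads were taken on an Illumina HiSeq. The markers used to sort the cells are not given in the sources used here. Reads were processed with Trimmomatic 0.35 and STAR 2.5.2a on mm10, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, whole numbers with no normalization, in 1 table with 1 column per library; no column was left unused. Total counts ranged from 5868728 to 15014104 per library. Of the 54837 gene identifiers in the table, 54722 matched a gene symbol and 115 did not. Gene positions are those of GENCODE release M21 on GRCm38, the assembly also called mm10, counted from 1.

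Libraries were grouped by the phase in their labels and numbered by the run in their titles. The 12 pairs of libraries within a group were compared for duplication. Their counts differed by 23.99 to 114.5 times the sampling noise (chi-square per degree of freedom), so no library was counted as a copy of another. The labels do not say whether the runs used separate animals, so p-values measure the spread between these samples, which may be partly technical.

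The main test, fixed before the data were examined, was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, two-sided) on counts scaled by TMM factors. Genes with low counts were removed with filterByExpr by group, which left 15192 genes. The main model held the phase alone, and p-values were adjusted by Benjamini-Hochberg at 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled, and per-run log2 ratios used a prior count of 2. The 42 gene lists, of pathways, mammary basal genes and markers of other cell types, were also fixed at that point. Lists with at least 5 tested members, 40 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Beside the count of members past the threshold over all tested genes stands the count adjusted over the list alone.

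The run numbers were checked for pairing. Deviations of log2 CPM from the group mean correlated between the G0 and G1 libraries of the same run at 0.668, 0.470, 0.638 and 0.437 for runs 1 to 4. Between different runs the highest correlation was 0.0971. The pairing therefore comes from the run number in the titles and from these correlations, and results of a fit with the run as a replicate block are printed beside those of the main model for genes and lists whose call differs.

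Genes named in the text follow a rule fixed at the same time. It takes the 15 largest rises and 15 largest falls past an adjusted p of 0.05 with a mean log2 CPM of at least 3 and the same sign in all 4 runs, passing over symbols of the form Gm with a number or ending in Rik. It adds the 4 members of each list with the smallest p and a set of cell cycle, basal and stem cell genes. The first part named no gene under the main model, so it was also applied to the blocked fit, a choice made after the main result was seen. Tagln, Gm48529, Gm38165, Gm43126, Gm10800 and the called list members Col1a1, Col1a2, Cox6c, Atp5e, Atp5k, Rpl39 and Ly6a lie outside the rule, as do Gpihbp1, Cd34, Ecscr and Tspan18 of a second endothelial panel, and were picked after their values were seen. Not every gene the rule takes is named in the text, and the choice among them was also made after their values were seen.

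Alternatives set at the outset were RLE size factors, no low-count filter, at least 10 counts in all 8 libraries, DESeq2 1.42.0, limma-voom, the replicate block, an absolute log2 fold change of at least 1 and each library left out in turn. For lists they were also an estimated correlation and fry. The same alternatives for the blocked fit, whole runs left out and offsets for transcript length and GC content were added after the data were seen. Length and GC of the longest transcript were known for 99.94% of tested genes. The tests were tried on simulated counts with known changes, drawn from the libraries' own means with their run effects, over 14844 genes. For G1 against G0 without the block, edgeR found 8.96% of genes changed 2-fold and 71.2% of those changed 4-fold. With the block it found 70.1% and 95.5%, and 7.05% of its 156 calls were false. The simulation was 1 set of counts, with dispersions from the blocked fit and genes drawn independently. Pairing was thus built in, so the gain from the block is no evidence for pairing in the real data.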

Results

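Gene expression was measured by RNA sequencing in basal cells of the mouse mammary gland, the outer epithelial layer of the ducts, which includes the contractile myoepithelial cells. The cells had been sorted into G0, the resting state outside the division cycle, and G1, the growth phase before DNA synthesis. Each of 4 runs gave 1 G0 and 1 G1 library. The G0 libraries of runs 1 to 4 held 10609474, 10530807, 15014104 and 5868728 counts. The G1 libraries held 13711195, 12599720, 10594434 and 6807090. The G0 library of run 4 had counts on 39094 genes, against 20836 to 26614 in the other 7 libraries.

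The comparison of G1 with G0 asks which genes differ between resting basal cells and those in the growth phase. Within each run, the median of contractile genes of myoepithelial cells and the cyclins Ccnd1 and Ccnd2, which drive passage through G1, were higher in G1, and the median of endothelial genes was lower. Of these genes, 12 of 19 contractile and 12 of 14 endothelial ones kept 1 sign in all 4 runs. Acta2, smooth muscle actin, averaged 7926 ± 1419 CPM in G0 and 12213 ± 2188 CPM in G1 (SD, n = 4). Ccnd2 averaged 117 ± 9.96 CPM in G0 and 194 ± 20.3 CPM in G1 (SD, n = 4). Cldn5, a tight junction protein of blood vessel endothelium, averaged 69.5 ± 21.8 CPM in G0 and 20.1 ± 10.5 CPM in G1 (SD, n = 4). The basal keratins Krt5 and Krt14 did not pass the test.

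Whether these differences passed the threshold depended on the run term and on the test. With the phase alone in the model, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p of 0.05, while 425 genes had an unadjusted p under 0.05, 156 higher and 269 lower in G1. Limma-voom also called 0 and 0, and DESeq2 called 10 higher and 24 lower. Among the latter's calls were Ccnd2 and Cldn5 (adjusted p = 0.00677 and 0.00718), while Acta2 and Ccnd1 did not pass (adjusted p = 0.347 and 0.359). With the run as a replicate block, edgeR called 73 genes higher and 116 lower, and all 189 had the same sign in all 4 runs. Of these, 15 were at least 2-fold higher and 91 at least 2-fold lower. The biological coefficient of variation was 34.9% without the block and 16.9% with it. Unless another fit is named, log2 fold changes below are G1 over G0 from the blocked edgeR fit, with standard errors and Benjamini-Hochberg adjusted p, and calls are those of that fit. None of the genes named below passed in the edgeR fit without the block. Counts adjusted over the list alone are also those of the blocked fit; without the block they were 0 in every list except the contractile one (3 higher), the G1 cyclins (1 higher), the endothelial one (12 lower) and the stem cell one (2 lower). With an estimated correlation between genes, 0 of the 40 lists passed camera with or without the block, and with the preset one 18 passed without it and 21 with it.

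Of the gene lists, the contractile one had the most members called higher in G1. Of 19 tested members of the list, 7 were called higher and 0 lower, 14 were higher when adjusted over the list alone, and 18 had a positive fold change, with a median of 0.39. Without the block, 3 were higher adjusted over the list alone. Actg2, enteric smooth muscle actin, had a log2 fold change of 0.98 ± 0.11 (adjusted p = 7.15e-06) and Acta2 one of 0.63 ± 0.10 (adjusted p = 0.000642). Cnn1, calponin, changed by 0.55 ± 0.10 (adjusted p = 0.00324) and Myl9, a myosin light chain, by 0.54 ± 0.11 (adjusted p = 0.00587). Acta2 (ENSMUSG00000035783) lies on chromosome 19 from 34241090 to 34255590 on the minus strand, and Actg2 (ENSMUSG00000059430) on chromosome 6 from 83512905 to 83536265. Camera placed the list higher in G1 with an adjusted p of 5.62e-12 without the block and 2.29e-16 with it, against adjusted p = 0.128 and 0.281 with an estimated correlation. Tagln, transgelin, rose by 0.49 ± 0.10 (adjusted p = 0.00758) at a mean of 2557 CPM. Gm48529, which overlaps it on the opposite strand, gave 0.50 at 2386 CPM, and the strand setting of the counting is not stated. Without run 4, 4 contractile genes were called, and Myl9 and Tagln had adjusted p of 0.056 and 0.061.

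**Figure D1:**
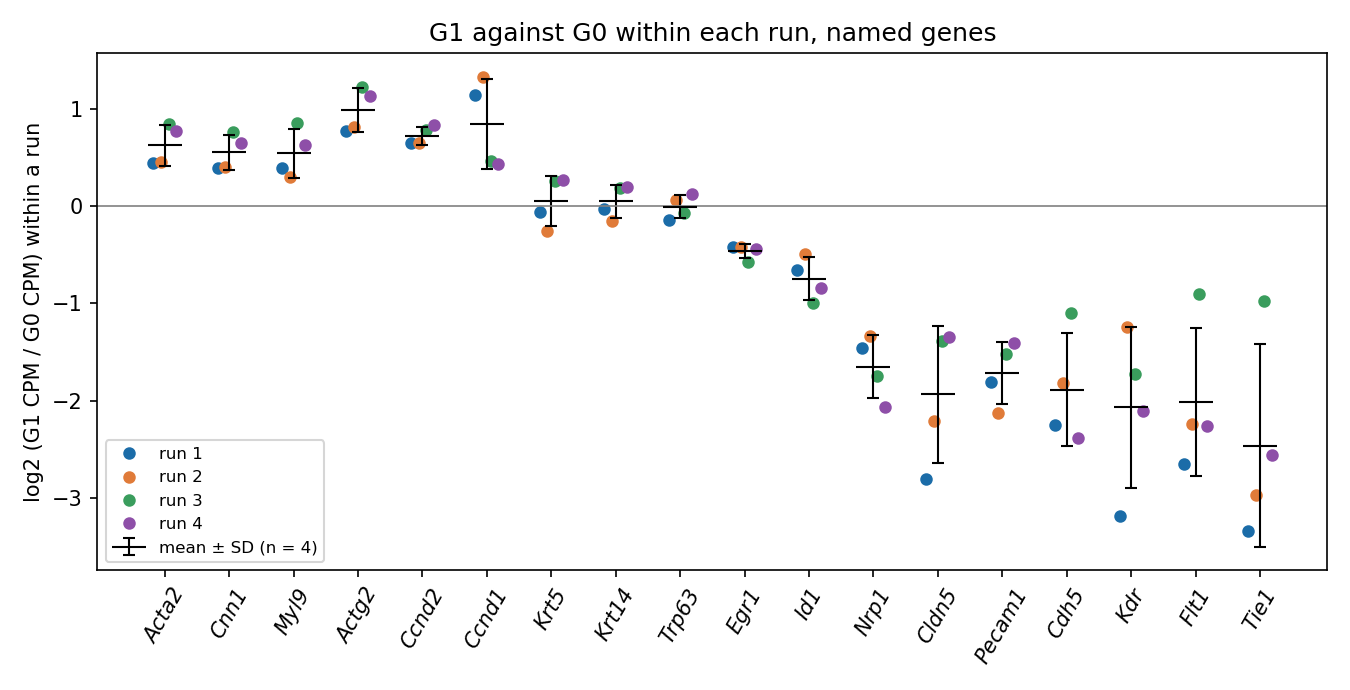
Log2 ratio of G1 to G0 CPM within each run (vertical axis) for 18 named genes, with a point per run and the mean ± SD over the 4 runs as a bar. Contractile genes and cyclins lie above 0 in all 4 runs, Krt5, Krt14 and Trp63 lie on both sides of 0, and the endothelial genes from Cldn5 to Tie1 lie below 0 in all 4 runs.

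Other lists of basal cell genes were measured beside the contractile one. Of 18 tested basal keratin and hemidesmosome genes, 0 were called, and the median was 0.02, while the mean was -0.0004 and camera's direction was down (adjusted p = 0.970). Krt5 had a log2 fold change of 0.05 ± 0.11, Krt14 of 0.05 ± 0.10 and Trp63, the transcription factor p63 of basal epithelium, of -0.01 ± 0.11. In the basement membrane list, 2 of 18 tested genes were called higher and 0 lower, Lama1 at 0.70 ± 0.13 (adjusted p = 0.00423) and the collagen IV chain Col4a1 at 0.53 ± 0.12 (adjusted p = 0.0263). The median of that list was -0.07, its mean -0.01 and camera's direction up (adjusted p = 0.576). Adjusted over the list alone, 3 were higher and 2 lower. With length and GC offsets camera placed both lists higher, at adjusted p = 0.0456 for the keratins (median 0.08) and 0.000145 for the basement membrane (median 0.15, 6 called higher). Estimated correlations were not tried with the offsets; in the blocked fit they gave the lists adjusted p = 0.980 and 0.799. Without run 3 or run 4, Col4a1 had an adjusted p of 0.154 or 0.0779.

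Of the D-type cyclins, 2 were called higher. Ccnd2 had a log2 fold change of 0.73 ± 0.11 (adjusted p = 0.000406) and Ccnd1 of 0.87 ± 0.19 (adjusted p = 0.0176), each positive in all 4 runs, and Ccnd3 of 0.15 ± 0.13 (adjusted p = 0.695). Without run 1 or run 2, Ccnd1 had an adjusted p of 0.0779 or 0.139. Ccnd2 (ENSMUSG00000000184) lies on chromosome 6 from 127125162 to 127152193 and Ccnd1 (ENSMUSG00000070348) on chromosome 7 from 144929931 to 144939925, both on the minus strand. The antisense gene Gm43126 overlaps Ccnd2, at a mean of 11.7 CPM against 156 CPM. These were 2 of 19 tested G1 cyclins, kinases and E2F genes, and 2 when adjusted over the list alone. Camera placed that list higher (adjusted p = 0.00197 without the block and 0.000729 with it), with adjusted p = 0.152 and 0.281 under an estimated correlation. Of 38 DNA replication genes and 30 mitosis genes, 0 were called, and 0 adjusted over the lists alone. Their medians were 0.07 and 0.23, and camera gave adjusted p of 0.184 and 0.0173 with the block, the latter 0.309 with an estimated correlation. The proliferation marker Mki67 was low, at 2.07 ± 1.39 CPM in G0 and 1.55 ± 0.88 CPM in G1 (SD, n = 4). Ccne1, at 0.58 ± 0.29, and Myc, at -0.01 ± 0.10, did not pass.

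Of 29 inhibitors and regulators of quiescence, 1 was called, Ddit4, an inhibitor of mTOR signalling, at -1.01 ± 0.22 (adjusted p = 0.0142, but 0.178 without run 1 and 0.0596 without run 2). Adjusted over the list alone, 3 were lower. Cdkn1a, which encodes p21, had -0.33 ± 0.11 (adjusted p = 0.140, but 0.0426 with length and GC offsets). Cdkn1b, encoding p27, had -0.08 ± 0.23, Cdkn1c, encoding p57, -0.16 ± 0.18, Rbl2 0.07 ± 0.15 and Foxo3 0.32 ± 0.23, with adjusted p of 0.627 or more. The list median was -0.03 (camera adjusted p = 0.285).

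Of the gene lists, the endothelial one had the most members called lower in G1. Of 14 tested endothelial genes, all 14 had a negative fold change, 12 were called lower, 13 adjusted over the list alone, and the median was -1.71. Without the block, 12 were lower adjusted over the list alone. Cldn5 changed by -1.93 ± 0.22 (adjusted p = 0.000603), Pecam1, the adhesion protein CD31, by -1.74 ± 0.19 (adjusted p = 4.33e-06), Cdh5, VE-cadherin, by -1.93 ± 0.25 (adjusted p = 3.99e-05) and the VEGF receptor Kdr by -2.02 ± 0.27 (adjusted p = 9.89e-05). The receptors Flt1 and Tie1 changed by -2.00 ± 0.24 and -2.43 ± 0.36, and Tie1 had an adjusted p of 0.062 without run 2 and 0.05004 without run 4. Cldn5 (ENSMUSG00000041378) lies on chromosome 16 from 18776847 to 18778262. Camera gave the list an adjusted p of 1.14e-39 without the block and 6.61e-51 with it. With an estimated correlation the adjusted p was 0.106 and 0.0915, and the directional fry test gave 0.152 and 0.0403. The levels were low, with Cldn5 the highest of the list in G0. Without run 2, 7 endothelial genes were called, and without run 4, 8.

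**Figure D2:**
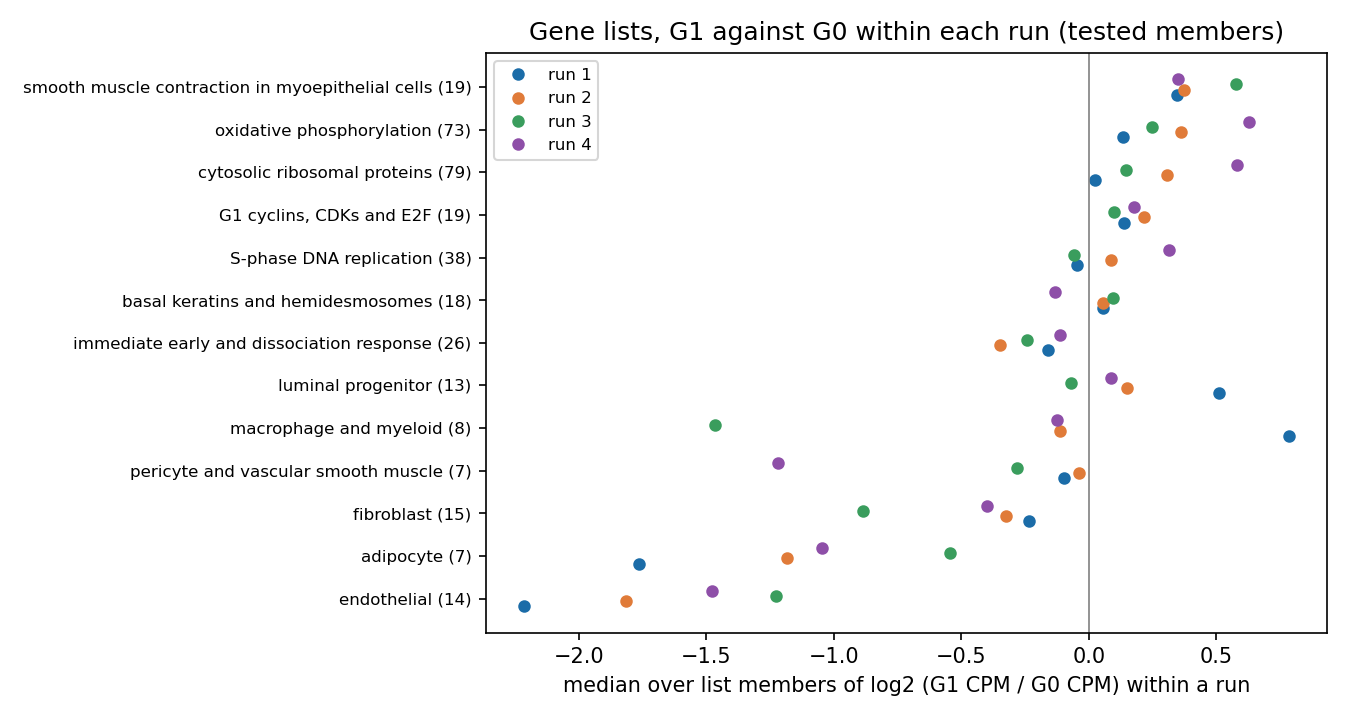
Median over list members of the log2 ratio of G1 to G0 CPM (horizontal axis) in each run for 13 gene lists, with tested members in brackets. The endothelial medians lie between -2.21 and -1.23 in the 4 runs, and the contractile medians between 0.34 and 0.58.

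Markers of other cell types were measured beside the endothelial genes. Of 15 fibroblast genes, 4 were called lower, Pi16, Lum, Col1a1 and Col1a2, and 0 higher. Adjusted over the list alone, 7 were lower and 2 higher. Col1a2 had an adjusted p of 0.195, 0.0783 and 0.0779 without run 2, 3 or 4, and of 0.0853 with length and GC offsets. In the fit without the block, the log2 fold changes of Col1a1 and Col1a2 turned positive, at 0.041 and 0.086, without the G0 library of run 3. That setting kept the G1 library of run 3 and so broke the pair. With whole runs left out of the blocked fit, Col1a1 stayed called, at -1.19 to -0.93 (highest adjusted p = 0.00483). Lum changed by -1.61 ± 0.28 (adjusted p = 0.0026), while Dcn, decorin, had 0.58 ± 0.16 (adjusted p = 0.0973, but 0.0178 without run 1 and 3.99e-05 without run 3). Of 7 adipocyte genes, 1 was called, the lipase Lpl at -1.20 ± 0.20 (adjusted p = 0.00158), and 4 were lower adjusted over the list alone. Fabp4 had -1.50 ± 0.27 (adjusted p = 0.0783, but 1.22e-09 without run 1). Camera placed both lists lower, with adjusted p of 0.0132 and 7.36e-05 without the block, and adjusted p = 0.698 and 0.176 with an estimated correlation. Of 12 markers of hormone-sensing luminal cells, 1 was called lower, Ly6a, also adjusted over the list alone. The median was -0.23 with the block and -0.51 without it (camera adjusted p = 0.0192 without the block, against adjusted p = 0.603 with an estimated correlation). By run it was -0.02, 0.11, -0.61 and -0.49. Medians of the luminal progenitor genes in runs 1 to 4 were 0.51, 0.15, -0.07 and 0.09. In the blocked fit these genes had a median of 0.33 over 13 tested, with 0 called. Adjusted over the list alone, 4 of these genes were higher and 1 lower. Camera called the luminal progenitor list higher with the block (adjusted p = 0.0157, and 0.503 with an estimated correlation) and not without it (adjusted p = 0.129). Of 7 pericyte genes 0 were called, with a median of -0.32, and camera placed them lower without the block (adjusted p = 0.0317) but not with it (adjusted p = 0.0909). The estimated correlation gave them adjusted p = 0.497 and 0.577. Medians were -0.14 over 8 myeloid, -0.24 over 5 lymphocyte and -0.22 over 7 Schwann cell genes, with 0 called in each and camera adjusted p of 0.289 or more. The runs differed in sign. In runs 1 to 4 the myeloid medians were 0.79, -0.11, -1.465 and -0.13. The lymphocyte medians were 1.01, 0.22, -1.03 and -0.91, so these summaries do not show equal immune content in the 2 phases. Of the milk protein list 3 genes could be tested, with 0 called, and of the erythrocyte list 0.

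The list of genes associated with mammary stem cells had 2 of 19 tested members lower and 1 higher, and 7 lower and 1 higher adjusted over the list alone. The lower genes were Nrp1, a VEGF co-receptor, at -1.67 ± 0.21 (adjusted p = 2.62e-05), and Cdh5, which is also on the endothelial list. The growth factor gene Nrg1 rose by 0.56 ± 0.13 (adjusted p = 0.0232, but 0.131 without run 3 and 0.16 without run 4). Procr had -0.87 ± 0.24 (adjusted p = 0.113, but 0.000118 without run 1, and above 0 in the fit without the block when the G0 library of run 3 was left out), Lgr5 -0.33 ± 0.11 (adjusted p = 0.171) and Axin2 0.01 ± 0.38. Camera placed the list lower (adjusted p = 0.00225 without the block), with adjusted p = 0.128 under an estimated correlation. Of 11 mesenchymal genes 0 were called. The repressors Zeb1 and Zeb2 had -1.43 ± 0.57 (adjusted p = 0.272) and -1.47 ± 0.54 (adjusted p = 0.228) and stayed under 3 CPM on average in both phases. Snai2, at 0.12 ± 0.12, Ovol1, at 0.03 ± 0.15, and Ovol2, at -0.20 ± 0.29, did not pass. Camera placed the mesenchymal list lower (adjusted p = 0.02 without the block), with adjusted p = 0.33 under an estimated correlation. Of 19 epithelial identity genes 0 were called, with a median of -0.11.

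Genes of the immediate early response, which tissue dissociation also induces, leaned lower in G1. Of 26 tested, 24 had a negative fold change, 2 were called, 8 adjusted over the list alone, and the median was -0.24. Egr1 fell by 0.47 ± 0.10 on the log2 scale (adjusted p = 0.0162) and Klf2 by 0.81 ± 0.19 (adjusted p = 0.0285), while Zfp36 had -0.38 ± 0.11 (adjusted p = 0.0843, but 0.0392 with length and GC offsets). Egr1 had an adjusted p of 0.0712 without run 1 and 0.087 with length and GC offsets, and Klf2 of 0.154 and 0.186 without run 2 or 4. Camera gave an adjusted p of 0.000458 without the block, and adjusted p = 0.698 with an estimated correlation. In the TGF-beta and BMP list 1 of 24 tested genes was called, the BMP target Id1 at -0.74 ± 0.13 (adjusted p = 0.00224), and 5 were lower adjusted over the list alone. In the Wnt list 1 of 27 was called, the secreted Wnt antagonist Sfrp1 at -0.48 ± 0.11 (adjusted p = 0.0257), with 1 lower and 1 higher adjusted over the list alone, and the median was 0.00. With any 1 run left out, Sfrp1 had an adjusted p from 0.0522 to 0.0848. In the interferon list the antiviral genes Ifit2, at -1.61 ± 0.31 (adjusted p = 0.00469), and Rsad2, at -1.30 ± 0.33 (adjusted p = 0.0451), were the 2 of 23 called, also adjusted over the list alone. Rsad2 had an adjusted p of 0.109, 0.179 and 0.12 without run 2, 3 or 4. Camera placed the interferon list lower with the block (adjusted p = 0.000144, and 0.503 with an estimated correlation) and not without it (adjusted p = 0.17). Its median was -0.21 with the block and -0.01 without it, and by run it was -0.42, -0.37, -0.38 and, in run 4, 0.19. In the G1 library of run 4, Ifit2 and Rsad2 stood at 8.81 and 9.11 CPM, against at most 2.22 and 2.15 in the other G1 libraries. The Notch, TGF-beta and cytokine lists were lower by camera without the block, with adjusted p of 0.00139, 0.0107 and 0.0227, against 0.264, 0.413 and 0.603 as adjusted p with an estimated correlation. In the Notch and cytokine lists 0 genes were called, and 5 and 1 were lower adjusted over the list alone. The endothelial list moved the same way as the lists of this paragraph that leaned lower, with a median of -1.71 and 12 of 14 genes called.

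Nuclear genes of oxidative phosphorylation leaned higher in G1 by a small amount. All 73 tested had a positive fold change, with a median of 0.34, of which 3 were called, Cox6c, Atp5e and Atp5k, at 0.52 to 0.55, and 59 were higher adjusted over the list alone, against 0 without the block. Ndufb3 had 0.51 ± 0.14 (adjusted p = 0.0723, but 0.0444 without run 1). Without run 2 the 3 called genes had adjusted p of 0.059 to 0.124, without run 4 of 0.246 to 0.265, and Atp5k without run 3 of 0.115. Of 79 cytosolic ribosomal protein genes, 77 were positive, with a median of 0.28, 1 was called, Rpl39, at 0.59 ± 0.14 (adjusted p = 0.0289, but 0.174 without run 2 and 0.244 without run 4), and 27 were higher adjusted over the list alone, against 0 without the block. Camera gave the lists adjusted p of 8.39e-19 and 6.46e-06 without the block, and adjusted p = 0.413 and 0.771 with an estimated correlation. Run 4 had the highest medians, 0.63 and 0.58, and without it 0 genes of either list were higher adjusted over the list alone. The medians of the blocked fit without run 4 were 0.24 for oxidative phosphorylation and 0.16 for ribosomal proteins. Translation factors and proteasome genes had medians of 0.13 and 0.20, with 0 called, also adjusted over the lists alone, and camera adjusted p of 0.00225 and 6.46e-06 without the block, against adjusted p = 0.698 and 0.603 with an estimated correlation. Without run 4 these medians were 0.08 and 0.12. Mitochondrially encoded mRNAs and cholesterol synthesis genes had medians of 0.35 and 0.17 and passed camera with the block (adjusted p = 5.61e-05 and 0.0172) but not without it (adjusted p = 0.127 and 0.0545), with 0 called and 4 and 0 higher adjusted over the list alone. With an estimated correlation the adjusted p was 0.448 and 0.281.

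The largest rises by the fixed rule were those of Cxcl13, a chemokine for B cells, and Igfbp2, which binds insulin-like growth factors. Cxcl13 (chromosome 5, 95956951 to 95961068) went from 1.98 ± 1.83 to 15.02 ± 9.17 CPM (SD, n = 4), a log2 fold change of 3.05 ± 0.32 (adjusted p = 4.33e-06). Igfbp2 (chromosome 1, 72824503 to 72852474) went from 159 ± 62.1 to 388 ± 59.8 CPM (SD, n = 4), or 1.36 ± 0.22 (adjusted p = 0.0355, but 0.059 without run 2). Ramp1, Uts2b, Capn6, Nrep, Hist1h2bc, Sostdc1, Ckb, Il17b and Krt23 rose by 0.76 to 1.25. Il17b overlaps the antisense gene Gm38165, which had 0.90. Without run 4, Ramp1, Capn6, Sostdc1, Ckb, Il17b and Krt23 no longer passed, with adjusted p from 0.056 to 0.17, nor did Capn6 with length and GC offsets (adjusted p = 0.121). Among the largest falls were Ptprb of the endothelial list, at -2.02 ± 0.25, and, outside the lists, Rasip1 at -1.75 ± 0.19 (adjusted p = 7.01e-06) and Lrrc32 at -1.73 ± 0.17 (adjusted p = 1.49e-06). Genes on no list were not assigned to a cell type, so the falls of Rasip1 and Lrrc32 are not shown to be separate from the endothelial one.

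Library quality differed between phases in runs 3 and 4. Gm10800, a predicted gene, took 8.13% of the counts of the G0 library of run 4 (95% exact binomial interval 8.111 to 8.155, counting error only), 1.71% of its G1 library and 1.19% of the G0 library of run 3, and at most 0.0129% elsewhere. Of 1731 olfactory and vomeronasal receptor genes, 1350 had a count in the G0 library of run 4, 613 in that of run 3, 297 and 79 in the G1 libraries of runs 4 and 3, and at most 62 in the others. Without both libraries of run 4, the blocked fit called 21 genes higher and 76 lower, of which 83 were among the 189, and the fit without the block 0 and 0.

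**Figure D3:**
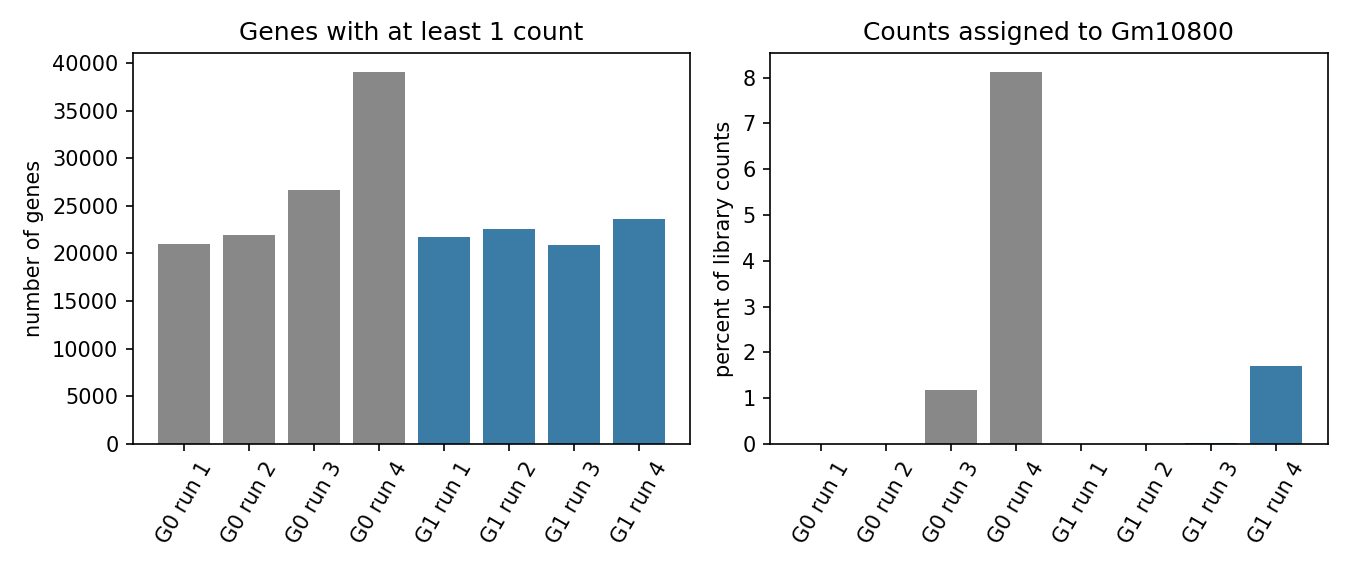
Number of genes with at least 1 count (left) and percent of counts on Gm10800 (right) in each library, G0 in grey and G1 in blue. The G0 library of run 4 has 39094 genes with a count and 8.13% of its counts on Gm10800.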

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

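The rule that compares each library with the 3 others of its phase was set at the outset, while the shares of Gm10800 and of receptor genes and the genes taken from the fit with the run block were chosen after the data were seen. Of 160 groups of 4 values examined, 25 held a library far from the rest. For independent, normally distributed values chance would give about 1 in 20 groups, or 8. These groups share the same libraries, and CPM and shares need not be normal, so an excess over chance is not established.

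Several of these concern library quality. Gm10800 took 8.13% of counts in the G0 library of run 4, against at most 1.19% in the other G0 libraries, and 1.71% in the G1 library of run 4, against at most 0.0129%. Olfactory and vomeronasal receptor genes with a count numbered 297 in the G1 library of run 4, against 35 to 79. The 10 genes with most counts took 13.3% of the G0 library of run 4 (95% exact binomial interval 13.31 to 13.37), against 5.93% to 6.88%.

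Run 3 held several genes apart from the other runs. In its G1 library Ccne1 stood at 14.4 CPM (others 4.14 to 5.46), Cdkn1a at 519 (276 to 296), Cdkn1b at 15.8 (4.83 to 5.31), Ovol2 at 7.15 (3.47 to 4.03) and Krt14 at 9800 (7630 to 7940). Procr stood at 96.5 CPM in its G0 library (6.17 to 18.0) and 28.3 in its G1 library (6.31 to 9.51). In its G0 library Snai2 was at 202 CPM (93.9 to 96.2), Lum at 32.4 (5.19 to 5.54), Col1a2 at 139 (29.5 to 45) and Krt23 at 19 (32.2 to 34.1).

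In the G1 library of run 4, Tagln stood at 3490 CPM (others 2770 to 2860), Capn6 at 53.8 (23.7 to 27.0), Zeb1 at 1.20 (0.408 to 0.537), Klf2 at 7.17 (11.1 to 11.2), Ifit2 at 8.81 (1.12 to 2.22) and Rsad2 at 9.11 (1.13 to 2.15). Sfrp1 was at 118 CPM in the G0 library of run 4 (167 to 172). In run 1 Sostdc1 was at 30 CPM in G0 (14 to 16.4), and in run 2 Ckb at 88.5 (49.0 to 54.7) and Klf2 at 22.5 (16 to 17), both in G0.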

How the results depend on the processing

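Alternatives to the fit without the block were planned, apart from leaving out run 4 whole; those of the blocked fit were chosen after the data were seen. Without the block, 0 genes were called higher and 0 lower with RLE factors, a minimum of 10 counts, limma-voom, a log2 fold change of at least 1, any single library left out and run 4 left out. The counts became 14 and 73 with no low-count filter, 10 and 24 with DESeq2, and 73 and 116 with the replicate block; the cause was not tested, though the block lowers the spread. DESeq2 shared 31 of its 34 calls with the blocked fit. Lists by camera numbered 7 higher and 11 lower. With an estimated correlation or fry they were 0 and 0, with no low-count filter 22 and 2, and with the replicate block 10 and 11, sharing 17 of 18 with the fit without it. Leaving out 1 library gave 4 to 13 higher (4 without the G0 library of run 2, 13 without that of run 3) and 2 to 13 lower (2 without the G0 library of run 3, 6 without the G1 library of run 2).

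For the blocked fit, the counts of 73 higher and 116 lower became 126 and 184 with no filter, 15 and 91 with a log2 fold change of at least 1, and 137 and 138 with length and GC offsets. Leaving out 1 run gave 21 to 99 higher (21 without run 4) and 76 to 175 lower (76 without run 4, 175 without run 1). With DESeq2 the counts were 97 and 136, with limma-voom 63 and 134. With the offsets the basement membrane, basal keratin and ribosome biogenesis lists passed camera as higher (adjusted p = 0.000145, 0.0456 and 0.034), and the luminal progenitor and mesenchymal lists did not pass (0.0672 and 0.0564). Without run 4 the mitosis, cholesterol and mesenchymal lists did not pass (adjusted p = 0.05009, 0.0627 and 0.136). Capn6, Egr1 and Col1a2 lost their call with the offsets, and Cdkn1a and Zfp36 passed. Blocked lists, 10 and 11, were 0 and 0 with an estimated correlation and 0 and 1 with fry. Endothelial genes lower numbered 7 to 13 with 1 run left out (7 without run 2). Contractile genes higher numbered 11 with the offsets and 4 to 7 with 1 run left out. Oxidative phosphorylation genes adjusted over the list alone numbered 59, and 0 to 54 with 1 run left out (0 without run 4, 35 without run 2).

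Of 792 values of 72 named genes without the block, 693 kept direction and side of the threshold, 62 newly passed (48 with the block, 14 with DESeq2), and 37, of 15 genes, turned sign. The fit without the block called 0 genes, so no call could be lost and the kept side is no sign of stable calls. With 1 library left out, log2 fold changes ranged from -0.36 to 1.45 for Ccne1, -0.089 to 0.069 for Myc, -0.76 to 0.53 for Cdkn1b, -0.43 to 0.23 for Cdkn1c, -0.032 to 0.16 for Rbl2, -0.13 to 0.45 for Snai2, -0.093 to 0.21 for Ovol1, -0.52 to 0.11 for Ovol2, -0.10 to 0.10 for Trp63, -0.080 to 0.14 for Krt5, -0.040 to 0.10 for Krt14, -2.03 to 0.12 for Procr and -0.43 to 0.30 for Axin2. Col1a1 ranged from -2.18 to 0.041 and Col1a2 from -1.27 to 0.086, above 0 without the G0 library of run 3. With whole runs left out of the blocked fit, both stayed below 0, at -0.93 and -0.45 or lower. Axin2 was at 0.0099 with the replicate block and -0.08 without it. Depth limits genes such as Mki67, Zeb1 and Zeb2, which stayed under 3 CPM on average. Zeb1 was too low to be tested with the block without run 4, and Zeb2 without run 1.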

Other observations

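The tests of the basal share and of pericytes, with and without run 4, the contrast with basal keratins, the run 4 test of oxidative phosphorylation and the gene counts of the splits were chosen after the results were seen, and the offsets and the leaving out of run 4 after the data were seen. The permutation p-values below come from shuffling genes between lists. They treat genes as independent and do not measure the spread between runs.

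Several lists fixed in advance showed no call with the block. Of 40 ribosome biogenesis, 18 glycolysis, 23 unfolded protein response, 28 autophagy and lysosome, 16 heat shock, 19 p53 target, 17 NRF2, 17 circadian clock and 17 YAP/TAZ target genes tested, 0 were called, and adjusted over the lists alone 1 heat shock gene was higher and 1 p53 target lower. Their medians were 0.05, 0.11, 0.08, -0.03, 0.03, 0.09, 0.05, -0.07 and 0.01, with camera adjusted p of 0.102 or more. Of the 116 genes lower in G1, 18 stood on lists of other cell types, 12 of them endothelial, and 90 on no list, while of the 73 higher genes 0 stood on a cell type list. The 7 contractile genes called higher were filed with the mammary basal lists, so this contrast depends in part on how the lists were drawn. The lists hold few markers each, and genes on no list were not assigned to a cell type. These counts therefore do not measure how many of the lower genes belong to endothelial or other cells.

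Endothelial genes had a negative median in all 4 runs. A lower share of basal cells in G0 with all other types alike is argued against for luminal, fibroblast, myeloid and lymphoid cells only, pooled over runs. The endothelial median differed from that of their pooled markers by -1.58 (permutation p = 1e-05, the smallest it can give). In runs 1 and 2 the myeloid, lymphocyte and fibroblast medians lay between -0.33 and 1.01. In run 3 they were -1.465, -1.03 and -0.89, beside an endothelial median of -1.23. In run 4 the lymphocyte median was -0.91, beside -1.48. For these types the pooled difference thus does not argue against that account in run 3. The pool left out the 7 adipocyte genes, whose median of -1.11 (SD 0.71) lay nearer the endothelial one, and the pericyte genes, at -0.32. DNA in the G0 library of run 4 is argued against as the whole cause by the 8 endothelial genes lower without run 4, and the medians were -2.21 and -1.82 in runs 1 and 2, where Gm10800 took at most 0.000429% of counts. Endothelial cells or their RNA in the G0 sort may account for the pattern. A second panel of 20 tested genes had a median of -1.01 with 19 negative (SD 0.59), just past the bound of -1 set beforehand. The panel was limited to endothelial genes not called in the blocked fit. Its members were thus screened on these same values, and its median is not an independent test. Gpihbp1, the most abundant of them at 38.3 CPM in G0 and 11.1 in G1, had -2.09, while Cd34 had -0.33, Ecscr -0.06 and Tspan18 0.22. The sort gate is not given here, and expression of these genes by resting basal cells themselves was not tested.

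Contractile genes had a positive median in all 4 runs. Dilution of basal RNA in G0 is argued against, since the contractile median lay 0.37 above the basal keratin median (0.367, permutation p = 3e-05), and a trend with length or GC by the 11 contractile genes called with offsets. In runs 1 to 4 the contractile medians were 0.34, 0.37, 0.58 and 0.35, against 0.05, 0.05, 0.09 and -0.13 for the basal keratin list. Vascular smooth muscle in the G1 sort was not tested, because its contractile genes are those to be explained. A larger share of pericytes in the G1 sort is argued against by the pericyte genes. Their median was -0.321 (SD 0.253, 6 of 7 negative, permutation p = 0.00038 against the contractile list), below 0 in all 4 runs (-0.10, -0.04, -0.28 and -1.22). This is weaker without run 4, at -0.0787 (SD 0.545, 4 of 7 negative) against 0.448 (permutation p = 0.00113), a distance smaller than that SD. A rise of the contractile programme with entry into G1, or a larger share of contractile basal cells in the G1 sort, may each be a candidate explanation; neither was tested.

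Oxidative phosphorylation genes had a positive median in all 4 runs, and their transcripts are short, with a median length of 1046 bases against 3097 for all tested genes. Length and GC offsets left a median of 0.267 (SD 0.098) from 0.34, so that trend is argued against as the whole cause. Run 4 alone is argued against by a median of 0.240 (SD 0.104) without it, but the 59 genes higher adjusted over the list alone became 0, with fewer libraries and a smaller fold, and camera gave an adjusted p of 1.96e-19 without run 4; with all runs the list had adjusted p = 0.309 with an estimated correlation. A difference in RNA quality between phases and a biological shift both stay open and were not tested.

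The calls were set against other splits of the 8 libraries into 4 and 4. Without the block the real split called 0 genes, which all 35 splits reach by construction, so the count of splits says nothing about that result. The highest other split, 184 genes, set runs 1 and 2 against runs 3 and 4, which points to a structure of the runs rather than of the phases. Lists by camera without the block numbered 18 in the real split, 7 of 35 splits gave as many, and the highest other gave 22, so chance cannot be excluded for the number of lists. The 7 other splits that also part all 4 runs gave 0 genes and at most 16 lists, and the 22 lists came from a split that parts 2 runs. With the block, 8 splits part every run, too few for a share under 0.05. The real split called 189 genes and the highest other 1, and for lists the real split gave 21 and the highest other 21, so 2 of 8 reached that number. That other split, which also gave the 16 lists without the block, keeps the phases of runs 2 to 4 apart and swaps only run 1. It still holds part of the difference between phases, so the tie cannot decide on chance.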
